A study of Staphylococcus aureus
Mus musculus with 8 samples.

How the data were processed

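RNA from 8 samples was measured on a custom Agilent array with 1 dye, holding probes for S. aureus and for mouse. Per the labels' protocols, cells were fixed in acetone and methanol, bacteria were opened with lysostaphin, RNA was extracted with TRIzol and labelled with Cy3 by an oligo-dT method. The deposited array files hold intensity values that the authors made with Agilent Feature Extraction 10.5.1.1. Per the file headers, the processed signal was background-subtracted and detrended within the array, with small surrogate values for spots not above background, and was not normalized between arrays. The deposited series values were checked and equalled the processed signal in 100% of values within 1e-06. The array held 15208 spots that were not controls, with 5678 probes for 2842 S. aureus genes and 3558 probes for 2280 mouse gene names. Spots with an outlier mark made up 0.0238%. No mouse annotation came with the data, so mouse genes are those the array files name.

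Groups followed the sample titles: infected for 2 h, 7 h and 18 h with 2 arrays each, and uninfected cells mixed with broth bacteria in stationary phase or in log phase, with 1 array each. For mouse genes both uninfected arrays formed 1 group. For S. aureus the reference was the mean of both broth arrays, and each lone array was assumed to vary like the infected ones. There were 13 comparisons, 6 of mouse genes and 7 of S. aureus genes. The groups, comparisons, gene lists, other settings to try and the rule for named genes were set before the data were examined.

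Signals were put on the log2 scale and scaled to each array's 75th percentile over the organism's probes that were well above background, by the scanner software's own mark, on all arrays. That left 86 mouse probes and 4 S. aureus probes for scaling, and 1084 mouse probes without the log-phase array. Probes well above background on at least 2 arrays were kept, and the brightest probe stood for its gene, which gave 1292 mouse and 998 S. aureus genes. Across arrays, the median correlation between 2 probes of a mouse gene was 0.811. Genes were compared with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8), and p-values were adjusted over all genes of a comparison by Benjamini-Hochberg with a threshold of 0.05. Values of single genes and lists are given less the median of all genes of the comparison, while p-values of single genes test the difference before that subtraction. Those medians were -0.01, -0.19 and 0.01 for mouse genes at 2 h, 7 h and 18 h against uninfected cells, and -0.19, -0.09 and 0.10 from 2 h to 7 h, from 2 h to 18 h and from 7 h to 18 h. For S. aureus they were 3.46, 5.02 and 5.10 against broth, 1.40, 1.47 and 0.06 between times, and -3.33 between phases.

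Of 22 mouse and 17 S. aureus gene lists written beforehand, 16 and 9 had at least 5 tested genes. They were tested with camera in limma at a preset correlation of 0.01, in 96 and 63 tests adjusted within each comparison, beside camera with an estimated correlation. The fry test asks whether the genes of a list move on balance one way and does not compare them with other genes. Lists with too few tested genes were left out. For mouse these were glycolysis and hypoxia (4 on the array), oxidative phosphorylation (0), cholesterol biosynthesis (0), cytosolic ribosomal proteins (3), autophagy (5) and markers of other cell types (17). For S. aureus they were quorum sensing and toxins (8), secreted enzymes (5), surface adhesins (5), iron acquisition (5), fermentation (0), purine and pyrimidine biosynthesis (10), amino acid biosynthesis and uptake (12) and capsule and biofilm (13).

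Named genes were those past the threshold with the largest change, up to 10 higher and 6 lower against uninfected cells, 6 each way against broth and 3 each way otherwise, where the replicates lay beyond both references. Where none passed, the 3 with the smallest p each way are given. Added to these were up to 4 members of each list discussed and a few genes fixed in advance. To keep the text short, lists other than chemokines, NF-kB, interferon-stimulated and immediate-early genes are given with 2 members, S. aureus list members only between phases, and genes fixed in advance only against uninfected cells or broth and between phases. Il6 and Lcn2, and hla and sigB, fell below the filter. The genes saeR, sarA and isdA are not named in the files.

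Alternatives were scaling over both organisms' probes, quantile normalization, normexp background correction with an offset of 50, no filter, a filter on all 8 arrays, the mean of a gene's probes, a 2-fold minimum, replicate and scan-session blocks, the deposited series values, either broth array as the reference, and leaving out each array. Added after seeing the data were leaving out the log-phase array together with the replicate block, leaving it out for gene lists, scaling over all S. aureus probes, and fold bounds against the stationary-phase array alone. The arrays lay on 1 slide in 2 scan sessions of 5 and 3 arrays. The second session held the replicates numbered 2, so replicate number and session were the same split among infected arrays. Pairing was checked by correlating, across genes, the differences between replicates at each pair of times. For mouse genes r was 0.662, 0.339 and 0.459, and for S. aureus genes 0.270, 0.204 and 0.238, so the replicate block was tried. With the replicate block 0 mouse genes passed in each of the 6 comparisons, and 590, 872 and 878 S. aureus genes were higher than in broth at 2 h, 7 h and 18 h.

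The tests were tested on simulated data in 20 runs with 200 changed genes. For mouse genes at 2 h against uninfected cells, changes of 1, 2, 3 and 4 on the log2 scale were recovered at 0.9%, 6.7%, 32.9% and 67.8%, with 2.75 false calls per run. Between 2 h and 7 h they were recovered at 1%, 6.2%, 32.4% and 67.6%. Without the log-phase array the recovery was 2.3%, 21%, 68.8% and 89.6% at 2 h, and 5.3%, 43.9%, 87% and 96.4% from 2 h to 7 h. For S. aureus at 2 h against broth it was 0.3%, 1.6%, 5.8% and 16.7%. A list of 20 genes shifted by 1 was called in 95% and 100% of runs for these mouse comparisons and in 40% for S. aureus. Simulated genes varied independently of each other, and no simulated array stood apart. These shares therefore do not cover lists of correlated genes or an array like the log-phase one. The other comparisons were not simulated.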

Results

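Gene expression of infected macrophages and of the bacteria inside them was measured on 8 arrays that carried probes for both organisms. RAW264.7 is a mouse macrophage-like cell line, and the bacterium was Staphylococcus aureus ATCC25923. Cells were taken 2 h, 7 h or 18 h after infection, with 2 arrays per time. The 2 other arrays held uninfected cells together with bacteria grown in LB broth. The titles give stationary-phase bacteria for one and log-phase bacteria for the other, while the free-text descriptions of these 2 samples give the phases the other way round. The titles' names are used here. The number of arrays limits the precision of every comparison, and since the labels do not say that replicates came from separate cultures, p-values measure only the spread between samples.

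The share of array signal on S. aureus probes was lower on infected arrays than on those with broth bacteria, and its size depended on how signal was taken. They held 3.78% of the summed processed signal at 2 h (SD 1.02, n = 2), 2.82% at 7 h (SD 0.145, n = 2) and 3.22% at 18 h (SD 0.342, n = 2). They held 44.7% on the stationary-phase array and 98.7% on the log-phase array, which have no replicates. From raw minus background signal the shares at 2 h, 7 h and 18 h were 17.6%, 17.2% and 19.0%, and over probes well above background on all 8 arrays 0.720%, 0.183% and 0.223%. A share of signal is not a share of RNA. Of the S. aureus probes, 5.83% and 9.39% were well above background at 2 h, 1.80% and 2.62% at 7 h, and 1.44% and 2.78% at 18 h. The share was 19.5% on the stationary-phase array and 53.1% on the log-phase array. Mouse probes were well above background at shares between 42.8% and 50.4% on the infected arrays and at 33.8% on the stationary-phase array. On the log-phase array only 5.37% of mouse probes were, and its scaled mouse values had a correlation of -0.0107 across genes with those of the stationary-phase array, against at least 0.909 between replicates of one time (genes are not independent replicates). Each comparison with uninfected cells is therefore also given against the stationary-phase array alone. Leaving out each array was planned for genes, and for gene lists this was chosen after seeing the data.

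**Figure D1:**
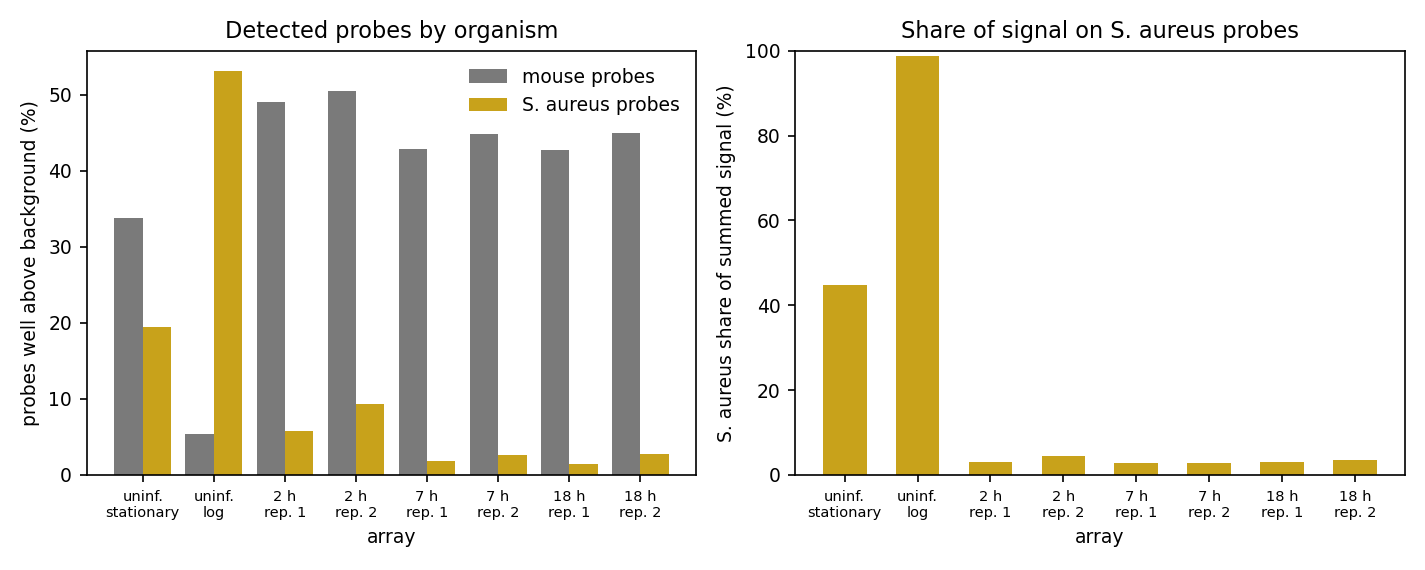
Left, the percent of mouse and S. aureus probes well above background on each array; right, the percent of summed signal on S. aureus probes. The infected arrays detected 42.8% to 50.4% of mouse probes, and the log-phase array 5.37%.

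What infection had done to macrophage transcripts after 2 h was asked by comparing the 2 arrays of 2 h with the 2 uninfected arrays. Transcripts for chemokines and for the NF-kB pathway were higher in infected cells as groups, while no single gene passed the threshold. Among chemokines and their receptors, the median of 14 genes lay 1.83 above that of all genes on the log2 scale, and 11 of them lay above it (adjusted p = 0.0017; adjusted p = 0.263 with an estimated correlation). Of these 14 genes, 4 passed when adjusted over the list alone and 0 when adjusted over all genes, and without the log-phase array 1 did. The NF-kB pathway and its feedback genes lay 1.64 above all genes, with 17 of 20 above the median of all genes (adjusted p = 0.000402; adjusted p = 0.263 with an estimated correlation). None of the 20 passed when adjusted over the list alone. Against the stationary-phase array alone the shifts of these groups were 1.62 and 1.43, and both passed again. LXR and lipid handling genes passed there alone, at 1.28 (9 genes; adjusted p = 0.0451; adjusted p = 0.415 with an estimated correlation). In tests against that 1 array the spread comes from the infected replicates, and with an estimated correlation no list passed against it at any time (smallest adjusted p = 0.219). The list of immediate-early genes did not pass at 2 h, though 2 of its 12 genes did when adjusted over the list alone.

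All gene values are log2 differences less the median of all tested genes of the same comparison, while p tests the difference before that subtraction and fold bounds are given without it. Beside each SE stands the value against the stationary-phase array alone, marked alone. Apart from Nfkbia, Socs3, Sod2 and Prdx2, the genes given with a value against uninfected cells at 2 h, 7 h or 18 h were at background on the log-phase array. Their first value therefore averages in a signal at background, and the value marked alone does not. Ccl4 was 6.0 higher at 2 h than in uninfected cells (SE 1.12, alone 4.34, n = 2 and 2; adjusted p = 0.198). Ccl3 was higher by 4.09 (SE 1.16, alone 2.50), Ccl2 by 3.82 (SE 1.08, alone 3.24) and Cxcl10 by 2.40 (SE 0.76, alone 2.59). Among NF-kB genes, Plaur was higher by 3.69 (SE 1.08, alone 2.31), Socs3 by 3.57 (SE 1.18, alone 4.21), Nfkbia by 3.15 (SE 1.04, alone 1.69) and Tnfaip3 by 2.23 (SE 0.78, alone 1.78). Gadd45g was at least 17.3-fold higher and Il1b at least 9.68-fold higher, since neither was well above background on an uninfected array, and at least 36.3-fold and 26.0-fold against the stationary-phase array alone. Such a bound sets the dim arrays to the lowest signal that counted as well above background on each. Cd83 was higher by 3.90 (SE 1.01, alone 2.79) and Tnf by 3.79 (SE 1.25, alone 1.88). Irf7, Cxcl2 and Ccl5 were higher by 1.56, 1.84 and 1.20, with SEs of 0.85, 1.03 and 0.86, and alone by 1.30, 1.53 and 0.93. Ptgs2 was at least 1.52-fold higher, and 4.08-fold alone. Magea9, Prf1 and Cntn1 were well above background on both uninfected arrays and on neither array of 2 h, but their signal did not fall with the mouse signal. From the stationary-phase to the log-phase array, which held little mouse signal, it changed by 1.37, 2.03 and -1.31 on the log2 scale, against a median of -4.26 over 836 genes, so no fold is given. Socs3 changed by -1.60 there.

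The 2 other groups that passed as higher at 2 h did so only while the log-phase array was used. Lysosomal and phagosomal genes lay 1.24 above all genes (36 genes; adjusted p = 0.0109; adjusted p = 0.631 with an estimated correlation) but 0.42 below them against the stationary-phase array alone, with a shift of -0.42 that passed as lower. In that list Cd68 was higher by 2.72 (SE 1.47) and Ctsl by 3.28 (SE 1.77), against 0.18 and 0.00 with the stationary-phase array alone. NRF2 and antioxidant genes lay 2.31 above all genes (8 genes; adjusted p = 0.0118; adjusted p = 0.631 with an estimated correlation) and 0.44 above them with the stationary-phase array alone, which did not pass. Mt1 and Mt2 were higher by 4.29 (SE 1.47) and 4.66 (SE 1.84), and by 1.80 and 1.84 against the stationary-phase array. None of these genes passed when adjusted over the list alone. Nos2 was well above background on 1 of the 2 arrays of 2 h and Il10 on both, and neither gene on an uninfected array. The signal of Il10 did not exceed the background limit of the uninfected arrays, so no bound is given.

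Of 1292 mouse genes tested at 2 h, 0 passed the threshold with limma, and 182 had an unadjusted p under 0.05. Without the stationary-phase array, which leaves the log-phase array as the sole control, 610 genes passed, and without the log-phase array 0 did. With the log-phase array left out and a replicate block, 4 passed: Ccl4, Myc and Pdcd1 were higher and Magea9 lower. Myc and Pdcd1 fall outside the rule for named genes and were chosen after their values were seen.

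At 7 h the question was the same, and interferon-stimulated genes had joined the groups that were higher in infected cells. Their 23 tested members lay 1.78 above all genes, with 20 above the median of all genes (adjusted p = 0.000133; adjusted p = 0.396 with an estimated correlation), and none passed when adjusted over the list alone, against 1 without the log-phase array. Chemokines and receptors lay 1.98 above all genes (adjusted p = 0.000252; adjusted p = 0.182 with an estimated correlation), and 4 of 14 passed when adjusted over the list alone against 0 over all genes, and 3 without the log-phase array. Against the stationary-phase array alone the shifts were 1.5 and 1.82, and both groups passed again. Ccl2 was higher by 5.48 (SE 1.08, alone 4.97, n = 2 and 2; adjusted p = 0.217), Ccl4 by 5.0 (SE 1.12, alone 3.4), Cxcl10 by 4.33 (SE 0.76, alone 4.59) and Ccl3 by 3.70 (SE 1.16, alone 2.17). Among interferon-stimulated genes, Igtp was higher by 3.73 (SE 0.91, alone 3.17), Usp18 by 3.64 (SE 1.13, alone 2.24) and Irf7 by 2.99 (SE 0.85, alone 2.80), and Zbp1 was at least 5.0-fold higher, and 13.3-fold alone.

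Of the genes that mark the early inflammatory response, Il1b was at least 9.20-fold higher at 7 h and Ptgs2 at least 1.38-fold higher, and alone 27.3-fold and 4.10-fold. Tnf was higher by 3.65 (SE 1.25, alone 1.81), Ccl5 by 2.04 (SE 0.86, alone 1.83), Nfkbia by 1.82 (SE 1.04, alone 0.43) and Cxcl2 by 0.57 (SE 1.03, alone 0.33). NF-kB pathway genes lay 0.90 above all genes (20 genes; adjusted p = 0.0287; adjusted p = 0.611 with an estimated correlation), but 0.35 above them and short of the threshold against the stationary-phase array alone. Plaur, Socs3 and Sod2 were higher by 3.68 (SE 1.08, alone 2.37), 3.37 (SE 1.18, alone 4.08) and 2.48 (SE 0.91, alone 1.69), and Socs1 at least 1.86-fold, and 5.54-fold alone. Lysosomal genes lay 1.24 above all genes (adjusted p = 0.0127; adjusted p = 0.611 with an estimated correlation), but with the stationary-phase array alone their shift was -0.52 and passed as lower. NRF2 genes lay 2.39 above (adjusted p = 0.0269; adjusted p = 0.611 with an estimated correlation) and unfolded protein response genes 2.18 above (7 genes; adjusted p = 0.032; adjusted p = 0.611 with an estimated correlation), which fell to 0.53 and 0.02 with that array alone and no longer passed. None of these 4 lists had a gene that passed when adjusted over the list alone. Ctsc and Vamp8 were higher by 2.17 (SE 0.99, alone 0.99) and 2.23 (SE 1.05, alone 0.82). Mt1 and G6pdx were higher by 3.55 (SE 1.47, alone 1.13) and 2.74 (SE 1.09, alone 1.21), and Calr and Hspa5 by 3.69 (SE 1.23, alone 2.02) and 3.62 (SE 1.71, alone 0.64).

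Cntn1, Cd97 and Magea9 were well above background on both uninfected arrays and on neither array of 7 h, and no fold is given for the same reason as at 2 h, since Cd97 too changed by only -0.67 between the uninfected arrays. Il10 was not above background on any of the 4 arrays, and Nos2 on 1 of them. In all, 0 of 1292 genes passed with limma, and 194 had an unadjusted p under 0.05. Without the stationary-phase array 634 passed, and without the log-phase array 0 did.

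By 18 h no inflammatory list differed from uninfected cells at the threshold. Against the stationary-phase array alone NF-kB genes lay 0.44 above all genes (adjusted p = 0.0445) and interferon-stimulated genes 0.44 above them (adjusted p = 0.0451), both at adjusted p = 0.504 with an estimated correlation. Ccl4 was still higher by 3.67 (SE 1.12, alone 2.11, n = 2 and 2; adjusted p = 0.466), Srgn by 3.73 (SE 1.20, alone 2.63) and Hyou1 by 2.63 (SE 0.94, alone 1.59). Tnf was higher by 2.53 (SE 1.25, alone 0.73), Ccl2 by 2.37 (SE 1.08, alone 1.90), Irf7 by 2.12 (SE 0.85, alone 1.96), Nfkbia by 1.75 (SE 1.04, alone 0.40), Ccl5 by 0.46 (SE 0.86, alone 0.30) and Cxcl2 by 0.42 (SE 1.03, alone 0.21). Ptgs2 was at least 1.66-fold higher, and 4.88-fold alone. Il1b, Nos2 and Il10 were each well above background on 1 of the 2 arrays. Cntn1, Cd97 and Magea9 were again found on both uninfected arrays and on neither array of 18 h.

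Lysosomal, NRF2 and unfolded protein response genes lay 1.32, 2.24 and 2.27 above all genes at 18 h (adjusted p = 0.0153, 0.0252 and 0.0321; adjusted p = 0.659, 0.578 and 0.578 with an estimated correlation). With the stationary-phase array alone, the lysosomal shift was -0.41 and passed as lower, and the others were 0.30 and 0.47 and did not pass. Calr and Hsp90b1 were higher by 3.30 (SE 1.23, alone 1.67) and 3.46 (SE 1.60, alone 0.93), and G6pdx and Prdx2 by 2.43 (SE 1.09, alone 0.94) and 2.16 (SE 1.14, alone 0.57). Ctsc was higher by 1.84 (SE 0.99, alone 0.70), and Ctsk was not above background on any of the 4 arrays. None of these 3 lists had a gene that passed when adjusted over the list alone. In all, 0 of 1292 genes passed with limma, and 126 had an unadjusted p under 0.05. Without the stationary-phase array 604 passed, and without the log-phase array 0 did.

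**Figure D2:**
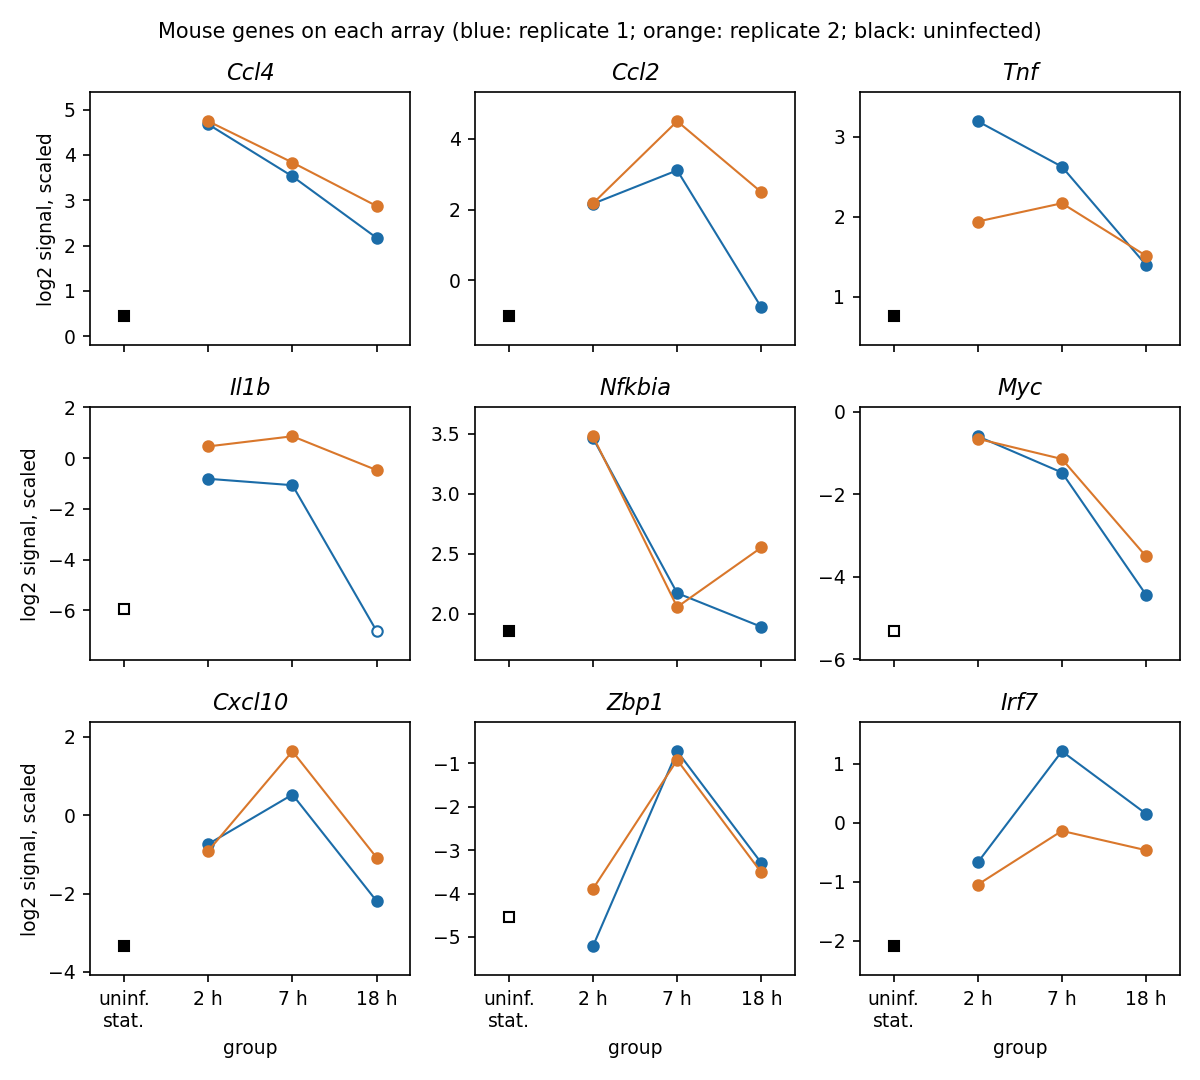
Signal of 9 mouse genes on each array on the log2 scale, scaled to the array's 75th percentile without the log-phase array; open symbols were not well above background. Ccl4 was highest at 2 h, and Cxcl10, Ccl2 and Zbp1 were highest at 7 h in both replicates.

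How the response moved on from 2 h to 7 h was tested directly between the infected arrays. Interferon-stimulated genes rose as a group while NF-kB and immediate-early genes fell. The 23 interferon-stimulated genes lay 1.46 above all genes, with 21 above the median, at 2.03 in replicate 1 and 0.98 in replicate 2 (adjusted p = 1.86e-20; adjusted p = 0.0598 with an estimated correlation). NF-kB pathway genes lay at -0.60 (adjusted p = 0.0023; adjusted p = 0.273 with an estimated correlation) and immediate-early genes at -0.50 (12 genes; adjusted p = 0.031; adjusted p = 0.273 with an estimated correlation). The immediate-early call ended without the log-phase array, at adjusted p = 0.218. Zbp1 was higher by 3.78 (SE 0.88, n = 2 and 2), Oasl2 by 3.42 (SE 1.04), Pml by 2.56 (SE 0.71) and Stat2 by 2.27 (SE 0.83), and Gbp3 was at least 6.27-fold higher. Cd83 was lower by 3.19, at -3.19 (SE 1.01), Malt1 at -2.29 (SE 0.78), Relb at -2.19 (SE 0.96), Tnfaip3 at -1.68 (SE 0.78), Nfkbia at -1.31 (SE 1.04) and Nfkb2 at -1.11 (SE 0.81). SEs of mouse genes between times pool the spread within all groups. They include the spread between the uninfected arrays, which lie outside these comparisons. The median SD within groups was 0.97 over mouse genes, and 0.55 without the log-phase array. Scaled without that array, Nfkbia stood at 3.46 and 3.48 in the replicates of 2 h and at 2.17 and 2.06 in those of 7 h. Atf3, Gadd45b and Dusp1 stood at -2.26 (SE 1.28), -1.48 (SE 0.97) and -1.32 (SE 0.74), Gadd45a went from both arrays well above background to 1, and Cd97 went from both arrays to none. No gene of these lists passed when adjusted over the list alone, and without the log-phase array 6 interferon-stimulated genes did. Of 1292 genes 0 passed with limma and 17 had an unadjusted p under 0.05, against 59 without the log-phase array.

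Between 2 h and 18 h chemokines, immediate-early genes and NF-kB genes fell as groups. Chemokines and receptors lay at -1.03 with none of 14 above the median of all genes (adjusted p = 3.29e-05; adjusted p = 0.0637 with an estimated correlation). Immediate-early genes lay at -1.12 (adjusted p = 2.95e-05; adjusted p = 0.0637 with an estimated correlation), and 1 of 12 passed when adjusted over the list alone against 0 over all genes. Without the log-phase array 1 gene of each of these lists did. NF-kB genes lay at -0.79 (adjusted p = 0.000145; adjusted p = 0.177 with an estimated correlation), and interferon-stimulated genes at 0.42 (adjusted p = 0.0382; adjusted p = 0.58 with an estimated correlation). Pdgfb went from both arrays well above background to 1. Gadd45g stood at -3.41 (SE 0.92, n = 2 and 2), Myc at -3.39 (SE 0.91), Egr2 at -2.59 (SE 0.95), Gadd45b at -2.25 (SE 0.97) and Dusp1 at -1.56 (SE 0.74). Ccl4 stood at -2.23 (SE 1.12), Ccrl2 at -1.37 (SE 0.90), Ccl2 at -1.35 (SE 1.08) and Cxcl2 at -1.32 (SE 1.03). The replicates of Ccl2 went opposite ways. Scaled without the log-phase array, it went from 2.16 to -0.76 in replicate 1 and from 2.17 to 2.49 in replicate 2. Plaur, Socs3, Nfkb1 and Tnfaip3 stood at -2.21 (SE 1.08), -2.20 (SE 1.18), -1.23 (SE 0.79) and -1.12 (SE 0.78). Cd48 was at least 3.98-fold and Prkdc at least 4.70-fold higher, and Tlr4 went from 1 array well above background to both. Oasl2, Ifih1 and Zbp1 were higher by 1.65 (SE 1.04), 1.51 (SE 0.87) and 1.11 (SE 0.88), while Ifnb1 was at least 2.48-fold lower. Of 1292 genes 0 passed with limma and 29 had an unadjusted p under 0.05, against 84 without the log-phase array.

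Between 7 h and 18 h chemokines and interferon-stimulated genes fell together. Chemokines lay at -1.43, at -1.43 in replicate 1 and -1.33 in replicate 2, again with none of 14 above the median (adjusted p = 1.52e-10; adjusted p = 0.0308 with an estimated correlation). Among the 16 lists and 6 mouse comparisons this was the 1 call that held with an estimated correlation. Interferon-stimulated genes lay at -1.0 with 1 of 23 above the median (adjusted p = 1.52e-10; adjusted p = 0.108 with an estimated correlation), immediate-early genes at -0.53 (adjusted p = 0.0136; adjusted p = 0.178 with an estimated correlation) and proinflammatory cytokines at -0.14 (19 genes; adjusted p = 0.0227; adjusted p = 0.179 with an estimated correlation). No gene passed when adjusted over a list alone. Without the log-phase array 1 chemokine, 1 immediate-early and 2 interferon-stimulated genes did. Ccl2 stood at -3.02 (SE 1.08, n = 2 and 2), Cxcl10 at -2.80 (SE 0.76) and Ccl5 at -1.48 (SE 0.86), and Ccl12 was at least 2.41-fold lower. Zbp1 and Igtp stood at -2.67 (SE 0.88) and -1.80 (SE 0.91), and Gbp3 and Gbp2 were at least 4.75-fold and 2.99-fold lower. Myc stood at -2.75 (SE 0.91), Fosl1 at -1.98 (SE 0.89), Egr2 at -1.72 (SE 0.95) and Il1rn at -1.73 (SE 0.92), and Il1b went from both arrays well above background to 1. Hyal1 and A930037G23Rik were each at least 4.19-fold higher, and Rb1 and Gadd45a went from 1 array well above background to both. Of 1292 genes 0 passed with limma and 8 had an unadjusted p under 0.05, against 53 without the log-phase array.

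**Figure D3:**
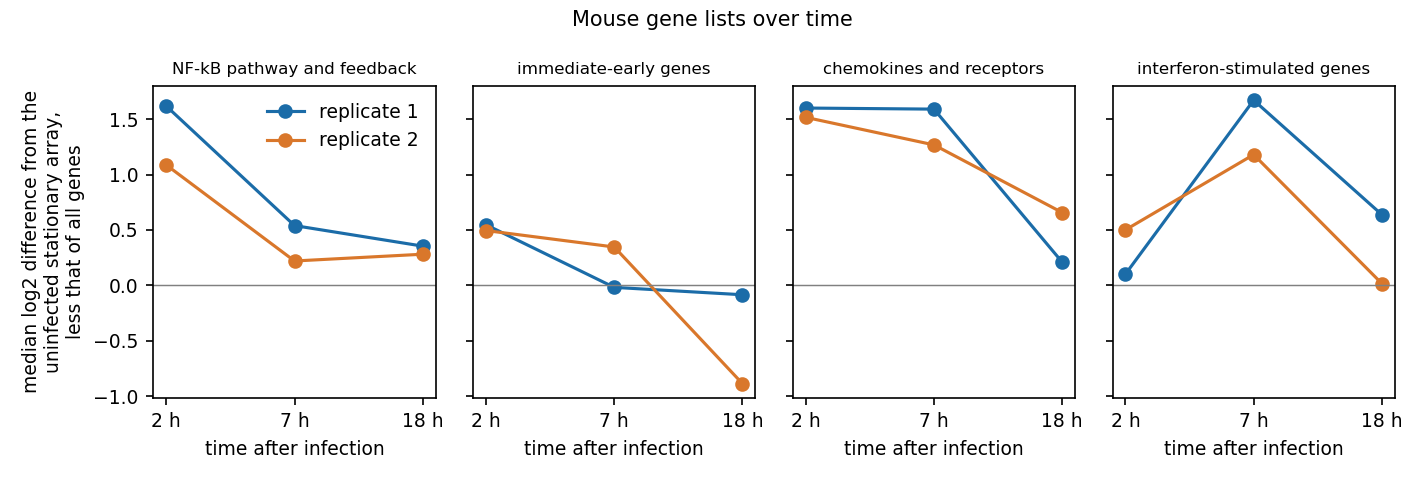
Median log2 difference of 4 gene lists from the stationary-phase array, less that of all genes, at each time in each replicate. Interferon-stimulated genes were highest at 7 h, and chemokines were lowest at 18 h.

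What the bacteria expressed inside macrophages was asked by comparing S. aureus genes on infected arrays with the mean of both arrays of broth-grown bacteria. The differences by which genes were named averaged arrays at background in 1 or both groups. Only detection is therefore given here for single genes on infected arrays. Their values in the section on processing show how far they moved with the setting and do not measure expression. At 2 h a putative epiD flavoprotein (SAOUHSC_01950) and a phage DnaC-like protein (SAOUHSC_02216) were well above background on both infected arrays and on neither broth array. The heme-degrading monooxygenase gene isdG, a putative phage antirepressor (SAOUHSC_02080) and a phosphotransferase system EIIA component (SAOUHSC_00214) were so on 1 of 2 infected arrays and on neither broth array. Of these 5 genes SAOUHSC_00214 alone had its other probe well above background on any infected array. Of 2836 genes with 2 probes, 5 had both well above background on both arrays of 2 h, 2 at 7 h and 1 at 18 h. Between the 2 probes of a gene, r was 0.129, 0.0454 and 0.0714 on replicate 1 of 2 h, 7 h and 18 h. On replicate 2 it was 0.502, 0.270 and 0.200, and on the stationary-phase and log-phase arrays 0.718 and 0.721. Signal on infected arrays was thus seldom shared by a gene's 2 probes. A putative teichoic acid biosynthesis protein (SAOUHSC_00642) was found on both infected arrays and 1 broth array. All S. aureus genes shared the SE of 1.62, since limma found no spread of the variance between genes.

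The regulator agrA, katA, clpB, sodA and spa were each well above background on 1 of 2 infected arrays at 2 h and on both broth arrays. In all, 436 of 998 genes were higher than in broth and 0 lower, but the median of all genes had moved by 3.46. The scaling rested on 4 probes. With scaling over both organisms' probes the median was -2.80 and 27 genes were higher and 626 lower. With scaling over all S. aureus probes 57 were higher and 219 lower, and with quantile normalization none passed and 121 had an unadjusted p under 0.05. Leaving out 1 array gave between 46 genes, without 18 h replicate 1, and 789, without the log-phase array. The count was 196 and 776 without replicate 1 or 2 of 2 h and 103 without the stationary-phase array.

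At 7 h SAOUHSC_00642 was well above background on both infected arrays and 1 broth array. SAOUHSC_02080, SAOUHSC_00214 and a putative phosphate-binding transport protein (SAOUHSC_01389) were well above background on 1 of 2 infected arrays and on neither broth array, the last by 1 probe while its other was dim on all infected arrays. isdG and SAOUHSC_02216 were not above background on any of the 4 arrays. clpB and spa were above background on 1 infected array, and agrA, katA and sodA on neither. In all, 821 of 998 genes were higher and 0 lower, with the median moved by 5.02. Only 55 and 89 of the 998 were well above background on the replicates of 7 h. Most of the 821 were therefore at background on both. With scaling over both organisms' probes 22 were higher and 637 lower, and with quantile normalization none passed and 199 had an unadjusted p under 0.05. The count was 539 and 369 without replicate 1 or 2 of 7 h, 210 without 18 h replicate 1 and 275 without the stationary-phase array.

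At 18 h the tRNA modification enzyme GidA (SAOUHSC_03052) was well above background on 1 of 2 infected arrays and 1 broth array. isdG and a phage protein (SAOUHSC_02064) were well above background on 1 of 2 infected arrays and on neither broth array, each by 1 probe while the other was dim on all infected arrays. SAOUHSC_02216, SAOUHSC_00214 and a superantigen-like protein (SAOUHSC_00386) were not above background on any of the 4 arrays. agrA, katA, clpB, sodA and spa were above background on neither array of 18 h. In all, 831 of 998 genes were higher and 0 lower, with the median moved by 5.10. Only 49 and 95 of the 998 were well above background on the replicates of 18 h. Most of the 831 were therefore at background on both. With scaling over both organisms' probes 26 were higher and 626 lower, and with quantile normalization none passed and 213 had an unadjusted p under 0.05. The count was 40 without 18 h replicate 1 and 288 without the stationary-phase array.

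**Figure D4:**
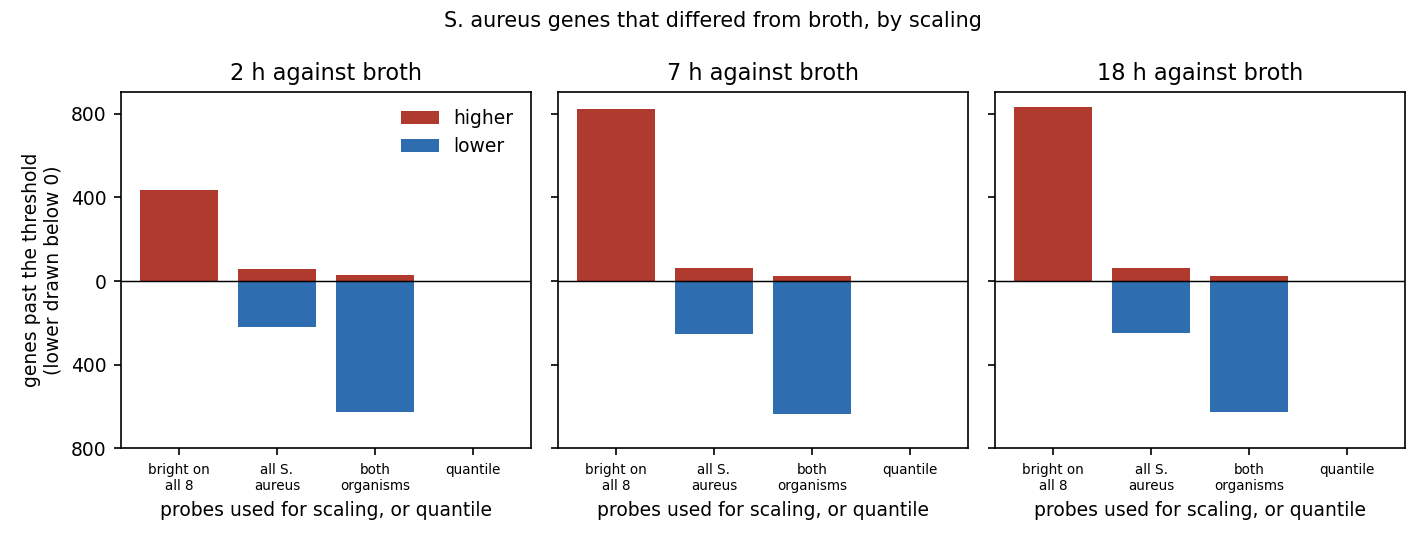
Number of S. aureus genes past the threshold against broth at each time, higher above and lower below 0, under 4 ways of scaling. At 2 h, 436 genes were higher with the planned scaling and 626 were lower with both organisms' probes.

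Of S. aureus gene lists against broth, 2 passed, but both were bright in broth and mostly at background inside macrophages, so their place relative to all genes does not measure a change of transcripts. Of 44 ribosomal protein genes, 40 and 44 were well above background on the broth arrays, 3 and 12 at 7 h and 1 and 13 at 18 h. Relative to all genes, they lay at -1.14 at 7 h (adjusted p = 0.0328; adjusted p = 0.84 with an estimated correlation) and at -1.44 at 18 h (adjusted p = 0.0226; adjusted p = 0.809 with an estimated correlation). The replicates gave -1.58 and 0.08 at 7 h, which go opposite ways, and -1.62 and -0.29 at 18 h. Before the median of all genes was subtracted, 29 and 27 of them were higher than in broth with the planned scaling, adjusted over the list alone. Adjusted over all genes 30 and 28 were, as were most tested genes. These counts follow the scaling and do not measure raised signal. Over all S. aureus probes the list's median before that subtraction was -2.51 at 7 h and -2.73 at 18 h, against 3.87 and 3.66 as planned. At 7 h 5 genes of oxidative and nitrosative stress lay at -2.05 (adjusted p = 0.0488; adjusted p = 0.84 with an estimated correlation). Before that subtraction 2 were higher with the planned scaling adjusted over the list alone, and 2 over all genes. None of these 3 calls held with scaling over both organisms' probes. At 2 h no list passed, and ribosomal proteins lay at -0.54 (adjusted p = 0.206).

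Change inside macrophages from 2 h onward was tested between the infected arrays. Ribosomal protein genes passed as lower relative to all genes from 2 h to 7 h, at -0.49 (adjusted p = 0.00275; adjusted p = 0.999 with an estimated correlation), and from 2 h to 18 h, at -0.56 (adjusted p = 0.00117; adjusted p = 0.827 with an estimated correlation). The replicates gave 0.06 and -1.35 at 7 h and -0.32 and -1.33 at 18 h, and no member passed when adjusted over the list alone. At 2 h 6 and 33 of the 44 were well above background, so these values too rest largely on signal at background at the later times. From 7 h to 18 h they lay at -0.07 and did not pass. Scaling over all S. aureus probes left the shifts as they were but ended both calls, at adjusted p = 0.185 and 0.09. With scaling over both organisms' probes both passed, at adjusted p = 0.0443 and 0.0176. rplS, a ribosomal protein gene, was found on both arrays of 2 h and on 1 each of 7 h and 18 h.

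From 2 h to 7 h the lower genes with the smallest p, none of them under 0.05, included SAOUHSC_00086, an acetoin reductase, and hld, the delta-hemolysin gene. Each was well above background on 1 array of 2 h and none of 7 h. ispD, lysS and a hydrolase (SAOUHSC_01279) were so on 1 array of 7 h and none of 2 h. From 2 h to 18 h the sensor kinase gene saeS went from both arrays to neither. An amino acid transporter permease (SAOUHSC_00732), SAOUHSC_03052 and a radical SAM protein (SAOUHSC_01185) were found on 1 array of 18 h and none of 2 h. From 7 h to 18 h, among the genes named as lower, SAOUHSC_01279, an autolysin precursor (SAOUHSC_00427) and ispD went from 1 array to none. In each of the 3 comparisons 0 of 998 genes passed with limma, and 16, 21 and 1 had an unadjusted p under 0.05, all of them higher at the later time with the planned scaling. The smallest adjusted p were 0.745, 0.708 and 1. Without 2 h replicate 1, 1 gene passed from 2 h to 18 h.

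Broth bacteria were compared between the stationary-phase and the log-phase array, 1 of each, so the p-values rest on the spread of the infected arrays and do not test the phases. The sign of each value turns if the descriptions rather than the titles are right. Heat shock and protease stress genes stood 2.36 above all genes on the stationary-phase array, with 8 of 9 above the median (adjusted p = 0.000375; adjusted p = 0.972 with an estimated correlation). Before the median of all genes was subtracted, the list stood at -0.98. The members given here were picked by the p of the difference before that subtraction. Relative to all genes clpB was higher by 4.73 (SE 2.29), hslO by 1.07, clpP by 1.00 and hslU by 0.83. Of these hslO, clpP and hslU lay below the list's 2.36. The gene htrA was above background on the log-phase array alone. Ribosomal protein genes stood at -0.93 (adjusted p = 0.0178; adjusted p = 0.972 with an estimated correlation), with rplO at -1.90, rplN at -1.88, rplQ at -1.82 and rplJ at -1.81. The ribosomal call ended with scaling over both organisms' probes (adjusted p = 0.466) and over all S. aureus probes (adjusted p = 0.1), while the heat shock call did not. No member of either list passed when adjusted over the list alone. A purine nucleoside phosphorylase (SAOUHSC_00097) was higher by 6.63 and a putative transcriptional regulator (SAOUHSC_01361) by 4.92, and SAOUHSC_01175 was above background on neither array. ulaA, of an ascorbate transporter, stood at -3.33, the nitrate reductase alpha subunit (SAOUHSC_02681) at -3.07 and a nitrite reductase (SAOUHSC_02684) at -2.90. katA was higher by 1.52, and sodA, spa and agrA stood at -0.06, -1.0 and -1.12. Of 998 genes 0 passed with limma (smallest adjusted p = 0.239) and 196 had an unadjusted p under 0.05, and the median of all genes was -3.33. Without either array of 2 h, 76 genes passed, all lower on the stationary-phase array. Direction followed the scaling used: over all S. aureus probes the median was 0.19, with 120 genes higher and 24 lower at an unadjusted p under 0.05, and with quantile normalization 0 had such a p. Without 18 h replicate 1 the median was -1.78 and 6 genes had one, without either array of 7 h 72.

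The other gene lists did not pass in any comparison with all 8 arrays. Among mouse lists the smallest adjusted p was 0.0898 both for antigen presentation and costimulation (17 genes) and for cell death (20 genes), 0.108 for antimicrobial effectors (10 genes) and 0.113 for macrophage identity (19 genes). It was 0.280 for cell cycle (7 genes) and for pattern recognition and inflammasome (26 genes), 0.327 for LXR and lipid handling and 0.581 for heat shock (5 genes). Among S. aureus lists it was 0.0611 for the TCA cycle (5 genes), 0.252 for SOS and DNA repair (9 genes) and for glycolysis and gluconeogenesis (5 genes), and 0.276 for global regulators (8 genes). It was 0.287 for cell wall, envelope charge and autolysis (6 genes) and 0.404 for ATP synthase, transcription and translation machinery (8 genes).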

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

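The lists below came from planned comparisons, while the tests of dilution, of little macrophage RNA, of scaling over few probes and of probe pairs among raised genes were chosen only after the result was seen.

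Differences between times after infection put 13 list results forward, each tested directly between times with camera. From 2 h to 7 h interferon-stimulated genes rose by 1.46 relative to all genes, and NF-kB genes stood at -0.60 and immediate-early genes at -0.50. With an estimated correlation their adjusted p was 0.0598, 0.273 and 0.273, and the immediate-early call also ended without the log-phase array. From 2 h to 18 h NF-kB genes stood at -0.79, chemokines at -1.03, immediate-early genes at -1.12 and interferon-stimulated genes at 0.42. With an estimated correlation their adjusted p was 0.177, 0.0637, 0.0637 and 0.58. From 7 h to 18 h chemokines stood at -1.43, interferon-stimulated genes at -1.0, immediate-early genes at -0.53 and proinflammatory cytokines at -0.14. Each of these 11 mouse results moved the same way in both replicates. They reuse the same lists over linked comparisons and were picked by the mean of these replicates, so equal signs are partly built in. With an estimated correlation chemokines from 7 h to 18 h passed (adjusted p = 0.0308), and none of the other mouse results did (smallest adjusted p = 0.0598). S. aureus ribosomal protein genes stood at -0.49 from 2 h to 7 h, where the replicates went opposite ways at 0.06 and -1.35, and at -0.56 from 2 h to 18 h, with most members at background at the later time. Neither call held with an estimated correlation (adjusted p = 0.999 and 0.827) or with scaling over all S. aureus probes (adjusted p = 0.185 and 0.09).

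The first pattern weighed was the little mouse signal on the array of uninfected cells with log-phase bacteria. The summed mouse signal, which on the log-phase array includes signal at background, changed by -3.63 on the log2 scale from the stationary-phase array. Lowered by that much, 100% of the 100 mouse probes brightest on the stationary-phase array would stay above background on the log-phase array. There 13% were (exact 95% interval 7.11% to 21.2%), which argues only against a uniform fall of that size and does not decide on dilution. A rank correlation across these probes was tried first and set aside, since most were at background. Their median log2 difference of -8.13 before scaling is a difference to signal at background, so next to no macrophage RNA and a far stronger dilution both stay open. Of 191 mouse probes well above background on the log-phase array, 51.3% were so on all 6 infected arrays (exact 95% interval 44.0% to 58.6%). Of all mouse probes 35.4% were. Binding of bacterial RNA to mouse probes stays open, and no biological explanation was tested.

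The second pattern was that 436 S. aureus genes were higher than in broth at 2 h and 0 lower with limma, where 572 had an unadjusted p under 0.05. With scaling over both organisms' probes 4.13% of the genes that differed were higher, but that scaling moved nearly all genes by the same log2 factor of -6.26, so it decides nothing about scaling over few probes. Of the 436 genes, 186 were well above background on neither array of 2 h, 221 on 1 and 29 on both. Among 435 with a second probe, 5.98% had both probes well above background on an array of 2 h (exact 95% interval 3.94% to 8.64%). Of 1814 genes with a probe well above background on the brighter log-phase array, 66.2% had both there. Unlike the 5.98%, that share leaves out genes with neither probe above background. So near background, the 5.98% neither supports nor excludes raised transcripts. Without a filter 2292 of 2842 genes were higher and 0 lower with the planned scaling. Only 998 genes had a probe well above background on at least 2 arrays, so genes short of that were called higher too. The one-sided count is therefore no measure of raised transcripts. Whether some of the 436 genes were raised, and how much scaling over few probes added, stays open.

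The third pattern was 36 S. aureus genes well above background on at least 2 infected arrays and on neither array with broth bacteria. The other probe was well above background on an infected array for 16.7% of them (6 genes, exact 95% interval 6.37% to 32.8%), below the 20% set beforehand as the bound against raised transcripts. The interval spans that bound, and asking that it lie wholly below was decided after the value was known, so raised transcripts stay open. On the brighter log-phase array, 66.2% of 1814 genes with a probe well above background had both. Of the 36 probes, 36.1% were brighter on the stationary-phase array, which held more mouse signal, than on the log-phase array (exact 95% interval 20.8% to 53.8%), against 16.9% of 2238 probes dim on all arrays. The bound set beforehand against binding of mouse RNA to these probes was a share of 50% or less, which 36.1% meets. That bound named no interval. The interval spans 50% but lies above the 16.9% of probes dim on all arrays. A share of 50% is thus not what dim probes showed, and the bound cannot decide. Such binding is left open.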

How the results depend on the processing

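Leaving out the log-phase array for gene lists, or with the replicate block, and scaling over all S. aureus probes were chosen after seeing the data. Of 200 gene values 168 were never reversed, of 31 list results 22, and of 20 comparison results 17. By the rule used, a comparison without genes past the threshold, a signal share or a count of list calls could not reverse. The 3 comparisons with broth, which could, reversed with scaling over both organisms' probes and over all S. aureus probes. Where the text below gives no reason, the cause was not tested. Values of Nos2 and Il10 against uninfected cells, and of agrA, katA and sodA at 7 h and these and clpB at 18 h against broth, rested on signal at background in 1 of the groups.

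Scaling over both organisms' probes gave 653, 659 and 652 S. aureus genes against broth at 2 h, 7 h and 18 h, mostly lower, and 15 mouse and 3 S. aureus list calls. The lysosome list kept its shifts of 1.24 at 7 h and 1.32 at 18 h relative to all genes, but camera's direction turned. Scaling over all S. aureus probes gave 276, 317 and 307 genes and 1 list call. Quantile normalization gave 0 at each time. It turned agrA to 0.67, clpB to 0.72 and katA to 0.44 at 7 h, katA to 0.27 at 18 h, sodA to 0.23 between phases, Nfkbia to -0.67 at 7 h and -0.62 at 18 h, Sod2 to -0.29 at 7 h and Prdx2 to -0.22 at 18 h.

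Normexp correction gave 992 S. aureus genes at 2 h and 1 mouse gene at 2 h. At 2 h it turned agrA to -0.72, katA to -0.60, Nos2 to 0.13 and Il10 to 0.0071. Between phases it turned htrA to 1.1, hslU to -0.35 and clpP to -0.39. Between 2 h and 7 h it turned Nfkbia to 0.33, Nfkb2 to 0.10 and Gbp3 to -0.12. Between 2 h and 18 h it turned Cxcl2 to 0.042, Ccl2 to 0.37, Zbp1 to -0.18, Cd48 to -0.34 and Prkdc to -0.17.

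Without a filter 6, 7 and 4 mouse genes passed against uninfected cells and 2292, 2660 and 2669 S. aureus genes against broth, from more genes tested. It turned agrA to -1.73 and katA to -2.18 at 2 h, hslU to -0.42, clpP to -0.25 and hslO to -0.18 between phases, Nos2 to 0.65, 1.13 and 0.50 at 2 h, 7 h and 18 h and Il10 to 1.14 at 2 h. With probes well above background on all 8 arrays 1, 1 and 1 S. aureus genes passed, from the few left. The mean of a gene's probes turned katA to -1.54 at 2 h and sodA to 0.12 between phases. Scan session as a block gave 708 S. aureus genes at 2 h and turned katA to -0.11 there and Il1b to -0.74 at 18 h.

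The log-phase array alone as reference gave 103, 275 and 288 genes and turned clpB to 1.05, 1.58 and 0.92 at 2 h, 7 h and 18 h and katA to 0.12 at 7 h. The stationary-phase array alone gave 789 at 2 h and turned katA to -0.59. With the log-phase array left out, with or without the replicate block, the lysosome list turned to -0.42, -0.52 and -0.41. With the block 4 mouse genes passed at 2 h, Nos2 turned to 0.55, 0.99 and 0.37 and Il10 to 1.19 at 2 h.

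Leaving out 1 array gave 0 to 610, 634 and 604 mouse genes at 2 h, 7 h and 18 h, the most without the stationary-phase array, and 46 to 789, 210 to 929 and 40 to 932 S. aureus genes against broth. It gave 0 to 1 from 2 h to 18 h and 0 to 76 between phases. At 2 h agrA ranged from -0.25 to 1.44, katA from -0.59 to 0.91 and clpB from -3.65 to 1.05. At 7 h they ranged from -1.20 to 0.063, from -1.38 to 0.12 and from -3.13 to 1.58, and at 18 h clpB from -3.85 to 0.92. Nos2 ranged from -2.79 to 0.55, from -2.24 to 0.99 and from -2.91 to 0.37 at the 3 times, and Il10 from -2.30 to 1.19 at 2 h. Cxcl2 ranged from -0.44 to 1.45 at 7 h, Ccl5 from -0.062 to 0.97 and Il1b from -2.39 to 3.96 at 18 h, and Ccl2 from -2.89 to 0.13 between 2 h and 18 h.

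Camera with an estimated correlation kept 1 mouse and 0 S. aureus list calls, and fry 2 and 0. Fry's values are medians not taken relative to other genes, which is why they turned to 2.97 for oxidative stress at 7 h, to 3.87, 3.66, 0.92 and 0.91 for ribosomal proteins at 7 h, at 18 h and from 2 h to 7 h and 18 h, and to -0.98 for heat shock genes between phases.

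The S. aureus share from raw minus background signal was 17.6%, 17.2% and 19.0% at 2 h, 7 h and 18 h, 50.8% on the stationary-phase and 93.1% on the log-phase array. Over probes well above background on all 8 arrays it was 0.720%, 0.183%, 0.223%, 66.7% and 94.7%. The ratio of median signals was 0.310, 0.362, 0.405, 0.900 and 5.73. Signal over background limited the S. aureus results, since few of its probes stood above background on infected arrays.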

Other observations

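The values here were looked at only after the data had been seen, and none was tested for a cause.

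Counting S. aureus genes with both probes well above background, replicate 1 had 20 at 2 h, 4 at 7 h and 1 at 18 h, and replicate 2 had 101, 17 and 9. In replicate 2, all 17 genes of 7 h were among the 101 of 2 h, all 9 of 18 h were among the 17, and all 101 were also found on the log-phase array and 97 on the stationary-phase array. In replicate 1, 8 of the 20 were found on the log-phase array and 6 on the stationary-phase array.

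Cntn1, Irak4, Magea9 and Prf1 were the 4 mouse genes well above background on both uninfected arrays and on no infected array. Their log2 differences between the log-phase and the stationary-phase array were -1.31, -0.02, 1.37 and 2.03, where 836 mouse genes found on the stationary-phase and all 6 infected arrays had a median of -4.26.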
